A study of Mus musculus with 4 samples.

How the data were processed

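RNA was measured in 4 libraries of mouse T cells (primary cells, strain C57BL/6NJ), which form 1 group. The labels call the assay total RNA-seq and link a library protocol whose name is that of a polyA+ method; which of these applies was not settled. The linked differentiation protocol is named for CD4+ T cells, per the labels' protocols. The labels give 4 biological replicate numbers, each with 1 technical replicate, and the sex as not collected.

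The authors deposited raw counts of read pairs per gene. Per the file headers, read pairs were counted with featureCounts 1.4.6-p4 on exons grouped by gene, with strand setting 2 (reverse-stranded), both mates required, and the GENCODE M13 annotation. Per the file headers the alignments came from STAR, whose version is not given in the sources used here, and no option for multi-mapping or multi-gene reads was recorded. The build is mm10 per the labels. The deposited exonic length of each gene was used for TPM. A pair of near-identical genes can lose reads to this counting, so such genes are uncertain.

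The plan, fixed before the data were examined, assumed deposited TPM and estimated counts. The files held whole-number counts, so TPM was computed from counts and exonic length, and counts were tested as deposited with no rounding. Symbols and gene types came from GENCODE M21, in which 50376 of 50600 gene identifiers matched; the 224 unmatched held at most 0.0111% of a library. Coordinates are those of the files. Totals ran from 46192242 to 63313389 read pairs. A count of 0 allows up to 3 counts of the total, and shares have Wilson intervals at 95% confidence. Intervals and limits cover counting error only.

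Spread between replicates was tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr, an intercept-only design and robust quasi-likelihood fits. Each gene's residual quasi-dispersion on 3 degrees of freedom was set against the trended prior by an F distribution with 13.9 prior degrees of freedom (upper tail), with Benjamini-Hochberg adjustment at 0.05. TMM factors lay between 0.9986 and 1.0006. The biological coefficient of variation is the square root of edgeR's common dispersion. DESeq2 1.42.0 gave alternative size factors and dispersion outliers. On simulated counts for the spread between the 4 T cell libraries (12131 genes), the test recovered 73 of 100 genes with an added SD of 0.5 log2, and 92 of 100 with 1 log2, and called 6 of 12085 others. The changed genes all had a mean count of 100 or more, so recovery at lower counts was not examined. Dispersions were drawn with about the prior degrees of freedom of the fit, so heavier tails were not simulated.

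Gene lists were fixed before the data were examined. List level is the median over members of mean log2(TPM + 1), and a member was detected at 1 TPM or more in every library. List spread is the median SD of log2 CPM (prior count 2) of members at a mean of 1 TPM or more, against 10000 random lists matched in 20 abundance bins; 25 of 30 lists had at least 3 such members. In 20 simulations without a changed list 1 of 500 lists was called, and a list with 3 times the deviations was called in 20 of 20. Lineage regulators were compared within libraries by exact two-sided sign-flip permutation over 11 pairs, of which 7 are reported.

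The genes named were set by rule: the 15 nuclear protein-coding genes with the highest mean TPM, the 4 highest members of each list, fixed lineage and cytokine genes, the sex-linked genes, and up to 15 protein-coding genes past the spread threshold at a mean of 5 TPM or more, by largest SD. Some genes set by this rule are left out of the text. Other genes are said to be chosen after their values were seen.

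For position along chromosomes, 11874 autosomal genes were scanned in 569 windows of 5 Mb at steps of 2.5 Mb with at least 15 genes. The statistic was the mean squared contrast, standardized in 20 abundance bins and limited to 6 units, over all 3 splits of the libraries into pairs, against 1000 permutations of gene positions. The segment of chromosome 4 was first noticed in an exploratory count of parted genes per 5 Mb bin. The scan settings were chosen after that, and the scan was not rerun with others. In simulations a window was called in 1 of 20 without a changed window and in 20 of 20 with 15 genes parted. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. Alternatives covered scaling, count filters, pseudocounts, detection floors, the spread test, gene subsets and each replicate left out.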

Results

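Gene expression was measured by RNA-seq in primary T cells of C57BL/6NJ mice, in 1 group of 4 libraries that the labels number as biological replicates 1 to 4. The file headers name the cells Th0, activated, at 16 h; Th0 is the usual name for helper T cells activated without cytokines that direct them to a lineage. The labels give 4 biosamples under a shared donor identifier and do not say whether these came from separate animals. The p-values of the edgeR and sign-flip tests therefore rest on the spread between these samples. Those of the list and position tests compare genes or gene positions within these 4 libraries, with genes as the units. With a single group there was no contrast between conditions, and the questions were which T cell genes the libraries held and how closely the replicates matched. The gene files held 53619400, 48931322, 63313389 and 46192242 counted read pairs in replicates 1 to 4. At least 1 TPM was reached in every library by 11181 genes, of which 9840 were nuclear protein-coding genes. Some results of the plan are left out of this text. Levels below are means ± SD over the 4 libraries (n = 4) in TPM (counts over exonic length, scaled to a fixed total) unless each library is given, in the order of replicates 1 to 4, and coordinates are mm10.

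The libraries held the transcripts of the alpha-beta T cell receptor and of the CD4 coreceptor at high level, and hardly any Cd8a. All 17 members of the T cell receptor and signalling list lay at 1 TPM or more in every library, with a median of 424 TPM. Trac, the constant region of the receptor alpha chain, reached 1883 ± 25.6 TPM and Trbc2, a beta chain constant region, 1241 ± 17.5 TPM. Cd5, a surface regulator of receptor signalling, lay at 1184 ± 40.4 TPM and the receptor-proximal kinase gene Zap70 at 822 ± 36.3 TPM. Trbc2 has a near-identical neighbour in Trbc1, so its level is uncertain. Cd4 (ENSMUSG00000023274.14, chromosome 6, 124864692 to 124888221) lay at 749 ± 30.2 TPM, Cd40lg, the ligand through which helper cells signal to B cells, at 370.4 ± 12.7 TPM, and Zbtb7b, a transcription factor of the CD4 lineage, at 87.3 ± 7.63 TPM.

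In the CD8 and cytotoxic list, 5 of 14 members were at 1 TPM in every library. Cd8b1 lay at 57.5 ± 3.71 TPM, Runx3 at 55.7 ± 4.41 TPM, Fasl at 40.6 ± 0.88 TPM and Nkg7 at 29 ± 4.83 TPM, whereas Cd8a (ENSMUSG00000053977.13, chromosome 6, 71373427 to 71379173) lay at 0.99, 1.06, 0.831 and 0.225 TPM. Within each library Cd4 exceeded Cd8a by 8.75 ± 0.395 on the log2(TPM + 1) scale, in 4 of 4 libraries (exact two-sided sign-flip permutation p = 0.13, the smallest that 4 libraries allow). Of the 7 gamma-delta T cell genes 1 was at 1 TPM in every library, Trdc, at 1.17 ± 0.0508 TPM; Sox13 lay at 0.588 ± 0.151 TPM, and Blk and Tcrg-C4 at 0.333 ± 0.21 TPM and 0.119 ± 0.198 TPM.

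Of 4 lineage regulators Gata3 stood highest and Tbx21 lowest. Gata3, the Th2 regulator (ENSMUSG00000015619.10, chromosome 2, 9857078 to 9890034), lay at 18.3 ± 0.919 TPM. Bcl6, the follicular helper regulator (ENSMUSG00000022508.5, chromosome 16, 23965052 to 23988852), lay at 6.88 ± 0.80 TPM, Foxp3, that of regulatory T cells (ENSMUSG00000039521.12, chromosome X, 7579676 to 7595243), at 2.93 ± 0.756 TPM, and Tbx21, that of Th1 cells (ENSMUSG00000001444.2, chromosome 11, 97098071 to 97115331), at 0.597 ± 0.412 TPM. Of the 11 within-library differences computed 7 are reported, among these 4 genes and between Cd4 and Cd8a, and all 7 had the same direction in 4 of 4 libraries. On the log2(TPM + 1) scale Tbx21 lay below Gata3 by a difference of -3.63 ± 0.347 and below Foxp3 by -1.31 ± 0.523, and Foxp3 lay below Bcl6 by -1.02 ± 0.282. Each of the 7 had an exact sign-flip permutation p of 0.13, so none can pass 0.05 in this design.

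The cytokines of polarised helper cells were near or under the detection limit. No read pair was counted in any library for Il4, Il17a or Il22, which allows up to 0.0474 to 0.0649 CPM in a library (3 counts of the total, counting error only). Ifng, the Th1 cytokine, lay at 0, 0.0522, 0.41 and 0.0575 TPM, Il13 at 0.515, 0.168, 0.22 and 0.0618 TPM, Il5 at 0.363, 0, 0 and 0 TPM, Il17f at 0.399, 0.0334, 0.157 and 0.516 TPM, Il21 at 0.0236, 0.0514, 0.0605 and 0.142 TPM, and Il10 at 0, 0, 0.0405 and 0 TPM. Cytokines of early activation were abundant: Il2, the T cell growth factor, lay at 438 ± 64.6 TPM, Lta at 359 ± 12.9 TPM, Tnf at 357 ± 3.95 TPM and Ltb at 282 ± 16.9 TPM, while Csf2 lay at 1.61 ± 0.572 TPM. In the lymphocyte cytokine list as a whole 7 of 18 members were at 1 TPM in every library.

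**Figure D1:**
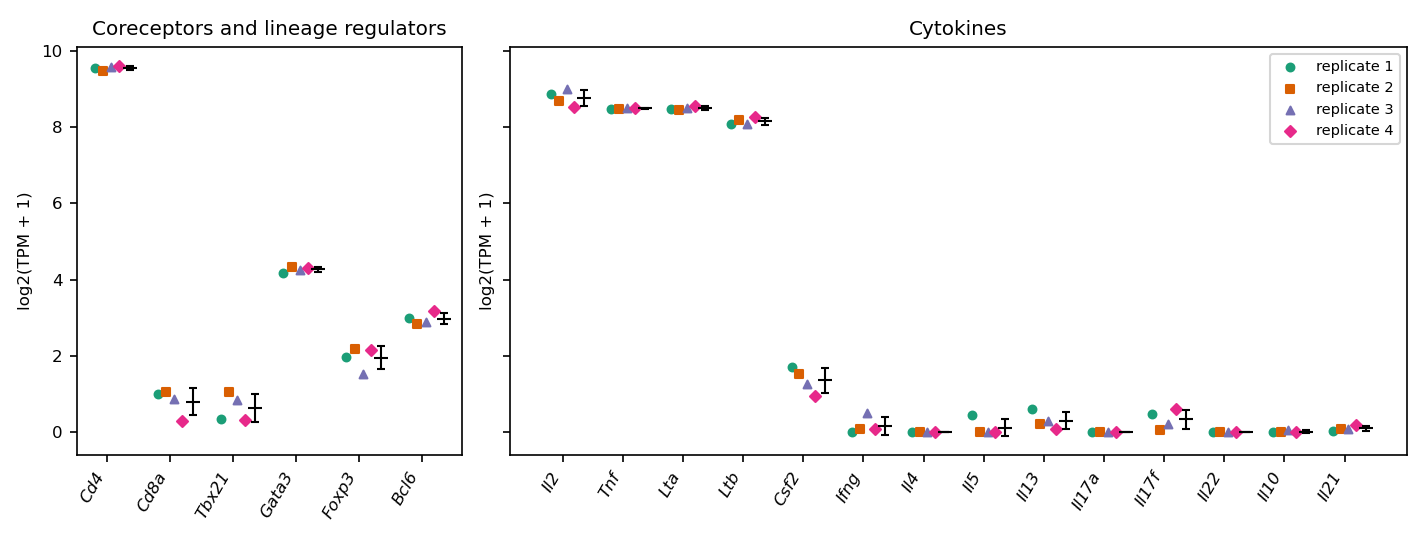
Level of coreceptor, lineage regulator and cytokine genes as log2(TPM + 1) on the vertical axis, with a coloured symbol for each of the 4 libraries and a black bar for mean ± SD (n = 4). Gata3 has a mean of 4.27 and Tbx21 of 0.64, and Il4, Il17a and Il22 lie at 0 in every library.

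The 5 helper lists were mixed. Of the Th1 list 5 of 12 members were detected in every library, among them Runx3, Stat4 at 28.8 ± 0.647 TPM and Il12rb2 at 1.74 ± 0.441 TPM. Of the Th2 list 6 of 12 were detected, led by Stat6 at 317 ± 13.7 TPM, Ccr8 at 128 ± 8.94 TPM, Il4ra at 113 ± 7.68 TPM and Ccr4 at 35.6 ± 2.46 TPM. Of the Th17 list 6 of 15 were detected, among them Irf4 at 1452 ± 91.9 TPM, Batf at 112 ± 2.39 TPM and Stat3 at 57.4 ± 2.62 TPM; Irf4 and Batf are also members of the activation list. Of the regulatory T cell list 12 of 14 were detected, led by Tnfrsf18 at 373 ± 15.6 TPM, Il2ra at 239 ± 13.9 TPM, Ctla4 at 128 ± 11.9 TPM and Capg at 80.3 ± 7.82 TPM. Of the follicular helper list 6 of 9 were detected, led by Pdcd1 at 216 ± 12.5 TPM, Icos at 99.9 ± 4.12 TPM, Sh2d1a at 26.6 ± 1.9 TPM and Slamf6 at 25.4 ± 1.64 TPM.

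Activation and naive-state genes were both present at high level. All 20 activation genes were detected in every library, with a median of 203 TPM; Irf4, Tnfrsf4 (OX40) at 1163 ± 69.7 TPM, Myc at 939.7 ± 51.1 TPM and the transferrin receptor gene Tfrc at 549 ± 41.2 TPM led the list. All 13 naive and quiescent genes were detected, with a median of 78.5 TPM, led by the lymph node homing receptor gene Ccr7 at 1297 ± 35.3 TPM, Tcf7 at 809 ± 31.5 TPM, Id3 at 401 ± 33.2 TPM and Bach2 at 179 ± 14.5 TPM. Of the inhibitory receptors 7 of 10 were detected, with Lag3 at 453 ± 24.9 TPM, Btla at 347 ± 11.1 TPM, and Pdcd1 and Ctla4 as above. Of the chemokine receptors 8 of 14 were detected; below Ccr7, Ccr8 and Ccr4 the next was Cxcr6 at 5.78 ± 1.89 TPM.

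All 15 glycolysis genes were detected in every library with a median of 362 TPM. Ldha, which makes lactate, lay at 2743 ± 92.7 TPM, Pkm at 1798 ± 68.6 TPM, Gapdh at 1477 ± 63.2 TPM and Aldoa at 1419 ± 66.4 TPM. All 22 cell cycle genes were detected with a median of 37.6 TPM, and the replication helicase genes Mcm3 (871 ± 48.8 TPM), Mcm5 (798 ± 24.6 TPM), Mcm6 (614 ± 23 TPM) and Mcm4 (599 ± 25.2 TPM) stood at the top. Of the heat shock and stress list 12 of 14 were detected, with the chaperone genes Hspd1 at 1865 ± 24.1 TPM, Hsp90aa1 at 1053 ± 27.5 TPM, Hspa5 at 963 ± 13.3 TPM and Hspe1 at 715 ± 24.5 TPM. Of the interferon response list 4 of 15 were detected, among them Bst2 at 257 ± 9.86 TPM, Ifit2 at 16.2 ± 1.1 TPM and Isg15 at 4.17 ± 1.5 TPM.

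Marker genes of other cell types were mostly below 1 TPM. None of the 10 neutrophil genes had a count in any library, including S100a8, S100a9, Ly6g and Mpo. None of the 7 NK cell genes and none of the 11 erythroid and platelet genes was at 1 TPM in every library; Eomes, Gzma, Ncr1 and Klra4 lay at 1.03 ± 0.421 TPM, 0.253 ± 0.264 TPM, 0.032 ± 0.0418 TPM and 0.0424 ± 0.0566 TPM, Itga2b at 1.24 ± 0.281 TPM and Klf1 at 0.391 ± 0.287 TPM. Of 10 stromal, endothelial and epithelial genes 1 was detected, Pecam1 at 9.78 ± 0.677 TPM; Epcam lay at 1.2 ± 0.35 TPM. Of 12 macrophage and monocyte genes 3 were detected, Cst3 at 75.8 ± 6.19 TPM, Ctss at 63.8 ± 3.88 TPM and Cd68 at 4.08 ± 1.82 TPM. Of 10 dendritic cell genes 3 were detected, Cd74 at 57.3 ± 2.99 TPM, H2-Ab1 at 3.37 ± 0.84 TPM and H2-Aa at 2.9 ± 0.872 TPM. Of 9 B cell genes 2 were detected, Ighm at 443 ± 18 TPM and Igkc at 14.8 ± 3.28 TPM, while Cd79a lay at 2.39, 2.46, 1.46 and 0.307 TPM. With 1 replicate left out, the detected members became 4 for B cells (without replicate 4), 2 for the stromal list (without replicate 1), 1 for NK cells (without replicate 3) and 1 for the erythroid list (without replicate 2).

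**Figure D2:**
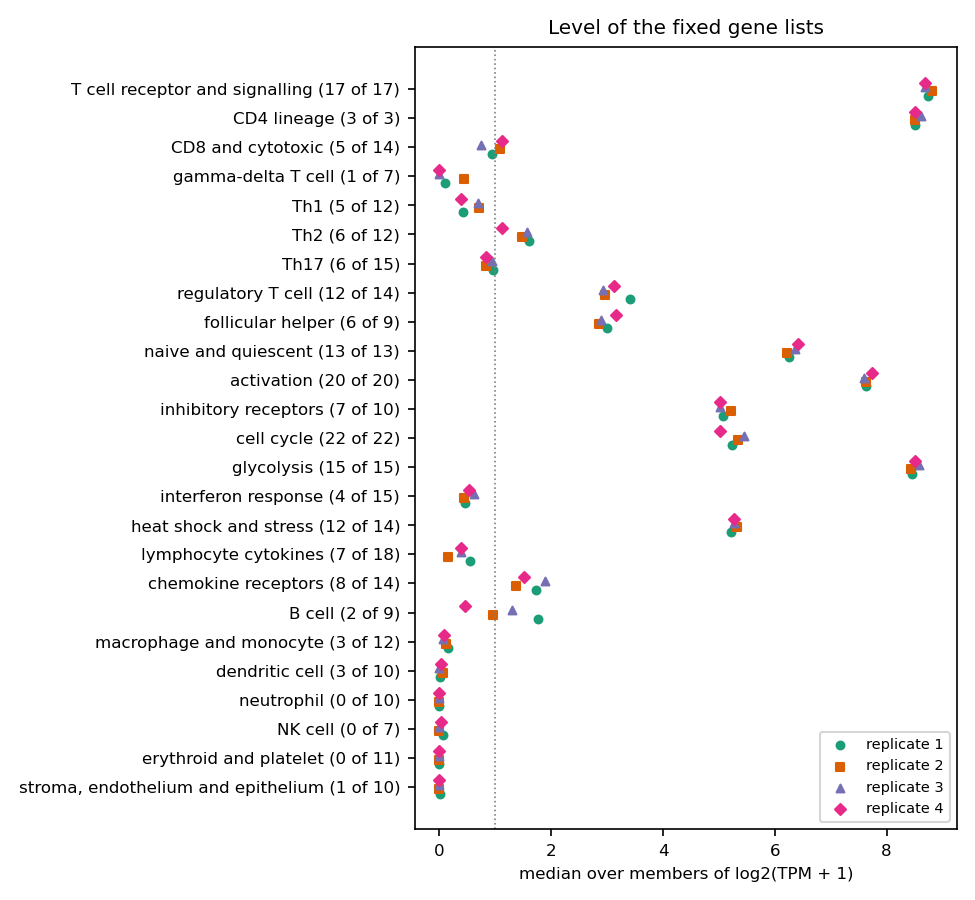
Median over the members of each fixed gene list of log2(TPM + 1) on the horizontal axis, with a symbol for each of the 4 libraries; in brackets, the members at 1 TPM or more in every library, and the dotted line marks 1 TPM. The T cell receptor, CD4 and glycolysis lists have means near 8.5 to 8.7, and the neutrophil and erythroid lists lie at 0.

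Eef1a1, the elongation factor that delivers aminoacyl-tRNA, was the most abundant nuclear protein-coding gene, at 13578 ± 614 TPM, Eef2 at 6863 ± 418 TPM and Eif5a at 3809 ± 198 TPM. Ribosomal protein genes supplied 9 of the 15 highest, from Rplp1 at 9905 ± 775 TPM and Rpl8 at 8566 ± 357 TPM to Rpl36 at 3077 ± 196 TPM, and 94 of 102 ribosomal protein genes were detected in every library. Hsp90ab1 lay at 9649.7 ± 345 TPM, Actb at 5948 ± 265 TPM and Npm1 at 3088 ± 62.6 TPM. Protein-coding genes held 98.8 ± 0.108% of read pairs, ribosomal protein genes 6.32 ± 0.343%, and the 10 most abundant genes 5.01 ± 0.0883%. Replication-dependent histones held 0.00236 ± 0.000178% with 13 of 63 genes detected, led by Hist1h2bj at 14.4 ± 2.97 TPM and Hist1h4i at 12.6 ± 2.6 TPM; histone genes have near-identical copies and are uncertain. Of 6 non-polyadenylated structural RNAs 4 were detected, with Rpph1 at 251 ± 87.5 TPM, Rn7sk at 11.8 ± 8.39 TPM, Rmrp at 1.93 ± 0.263 TPM and Terc at 1.87 ± 0.0791 TPM. Whether the libraries were polyA+ selected was not settled, so these histone and structural RNA levels cannot be read as those in the cells. At a floor of 5 TPM the detected members of several lists fell by more than 1.5 times: regulatory T cell to 7, histones to 6, Th1 and chemokine receptors to 3 each, dendritic cell and structural RNA to 1 each, and gamma-delta T cell to 0.

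Mitochondrial genes held 0.558%, 0.505%, 0.546% and 0.664% of read pairs in replicates 1 to 4, with 95% Wilson intervals from 0.556 to 0.560%, 0.503 to 0.507%, 0.544 to 0.548% and 0.662 to 0.666%. The intervals cover counting error only. mt-Co1 lay at 5147 ± 736 TPM, mt-Nd1 at 3219 ± 364 TPM, mt-Cytb at 2051 ± 374 TPM and mt-Nd2 at 1605 ± 194 TPM. Of the 13 mitochondrially encoded protein genes 6 were below 1 TPM in some library and 4 of these had no count at all. The counting recorded no option for multi-mapping or multi-gene reads, so the levels of these 6 genes are uncertain. The mitochondrial share includes these genes and may be too low, which the intervals do not cover.

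The 4 replicates were separate libraries and matched closely across genes. Pearson's r of log2(TPM + 1) over 20867 genes lay between 0.990 and 0.992 in the 6 library pairs, and Spearman's rho between 0.947 and 0.95; genes are not independent replicates. Between 1.5% and 1.84% of genes at 1 TPM in both libraries of a pair differed by more than 2-fold. Chi-square per degree of freedom of the counts lay between 8.71 and 22, so all pairs differed by more than counting noise. The biological coefficient of variation from edgeR was 0.0881. Among 11366 tested genes at a mean of 1 TPM or more, the median SD of log2 CPM was 0.0948.

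Sex-linked genes varied most between the replicates. Xist, the RNA that silences an X chromosome (ENSMUSG00000086503.3, chromosome X, 103460375 to 103483217), lay at 141, 116, 0.269 and 0.303 TPM in replicates 1 to 4 (SD 5.08 on the log2 CPM scale, adjusted p = 3.33e-15 from edgeR's quasi-likelihood residual spread). The Y-linked genes Ddx3y (0.0597, 0.104, 39.7 and 42.8 TPM), Eif2s3y (0.0149, 0.179, 49.2 and 46.5 TPM), Kdm5d (0.0205, 0.0312, 10.4 and 10.5 TPM) and Uty (0, 0.0138, 5.62 and 5.01 TPM) had the opposite pattern, and Tsix lay at 0.0306, 0.0111, 0.0524 and 0.0245 TPM. The 4 Y-linked genes were outside the main test, which needs a count minimum in every library. With that minimum in 1 library their edgeR adjusted p lay from 2.32e-11 to 1.15e-08, in a test chosen after the data were seen. They entered it only through the libraries where they lay high, so these values are no independent support. The X-linked genes Mid1 (13.8, 20.2, 6.26 and 2.03 TPM), Eif2s3x (133, 133.99, 89.8 and 89.2 TPM), Kdm6a (29.1, 27.7, 17.7 and 18.3 TPM) and Kdm5c (167, 169, 113 and 132 TPM) also passed, with adjusted p of 6.18e-07, 0.00258, 0.00794 and 0.0182. Of 3 other X-linked genes that are known to escape inactivation and were looked at after the data were seen, none passed: Ddx3x lay at 603, 588, 619.6 and 619 TPM, Pbdc1 at 33.6, 34.6, 33.7 and 28.2 TPM and 5530601H04Rik at 4.26, 4.49, 3.13 and 3.71 TPM (adjusted p = 0.998, 0.873 and 0.957). Mid1 reaches into sequence shared by X and Y, and Gm47283 (31.1, 14.5, 37.5 and 44.8 TPM; adjusted p = 0.0182) lies in such sequence, so both are uncertain.

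**Figure D3:**
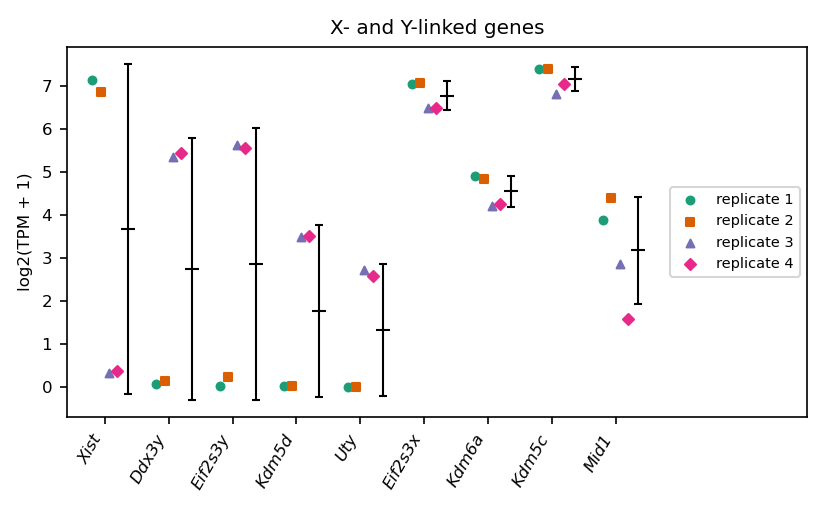
Level of X- and Y-linked genes as log2(TPM + 1) on the vertical axis, with a symbol for each of the 4 libraries and a black bar for mean ± SD (n = 4). Xist lies at 141 and 116 TPM in replicates 1 and 2 and under 1 TPM in replicates 3 and 4, where the 4 Y-linked genes lie high.

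In all, 28 of 12285 tested genes (0.228%) varied more between replicates than genes of like abundance (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), and 19 of them were protein-coding. Of 18 protein-coding genes at a mean of 5 TPM or more, the 15 with the largest SD are named here and above. Alpl, alkaline phosphatase (ENSMUSG00000028766.10, chromosome 4, 137741733 to 137796384), lay at 21.4, 77.1, 22.9 and 88.4 TPM (adjusted p = 1.55e-07). Bin2 (ENSMUSG00000098112.7, chromosome 15, 100641077 to 100669553) lay at 120.2, 213, 120.3 and 231 TPM (adjusted p = 5.79e-05) and the tubulin gene Tuba1c (ENSMUSG00000043091.8, chromosome 15, 99029891 to 99038105) at 211, 132, 199 and 129 TPM (adjusted p = 0.00270). Ece1 lay at 29.9, 50.9, 34 and 54.9 TPM (adjusted p = 0.00320), Clic4 at 52.6, 36.9, 49.9 and 36.1 TPM (adjusted p = 0.0378) and Cdk5rap1 at 31, 27.3, 18.7 and 38.2 TPM (adjusted p = 0.0244). The chemokine gene Ccl4 lay at 582, 571, 557 and 376 TPM and Pclaf, a PCNA-binding factor, at 20.8, 22.5, 27.6 and 14 TPM (adjusted p = 0.018 and 0.0223). The long genes Kmt2d (74.6, 62.8, 61.6 and 97.5 TPM) and Ubr4 (78.9, 77.6, 66.3 and 109 TPM) had adjusted p of 0.0180 each, which became 0.0927 and 0.0707 after removal of a length and GC trend. Alpl, Mid1, Bin2, Tuba1c, Ece1 and Eif2s3x passed under all alternatives that tested them, and the other 9 named genes each missed the threshold under 2 to 4. None of these alternatives tested whether reads were shared between Tuba1c and neighbouring tubulin genes. Without replicate 3 the count of 28 became 14, and Ccl4, Pclaf, Cdk5rap1, Kdm6a, Kdm5c, Clic4, Kmt2d and Ubr4 missed it with edgeR adjusted p from 0.0539 (Ccl4) to 0.982 (Cdk5rap1); without replicate 4 Ccl4, Pclaf, Kmt2d and Ubr4 missed it (0.411 to 0.997), without replicate 2 Gm47283 (0.889) and Kdm5c (0.0540), and without replicate 1 Kdm6a (0.0548), Kdm5c (0.0547) and Clic4 (0.176).

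**Figure D4:**
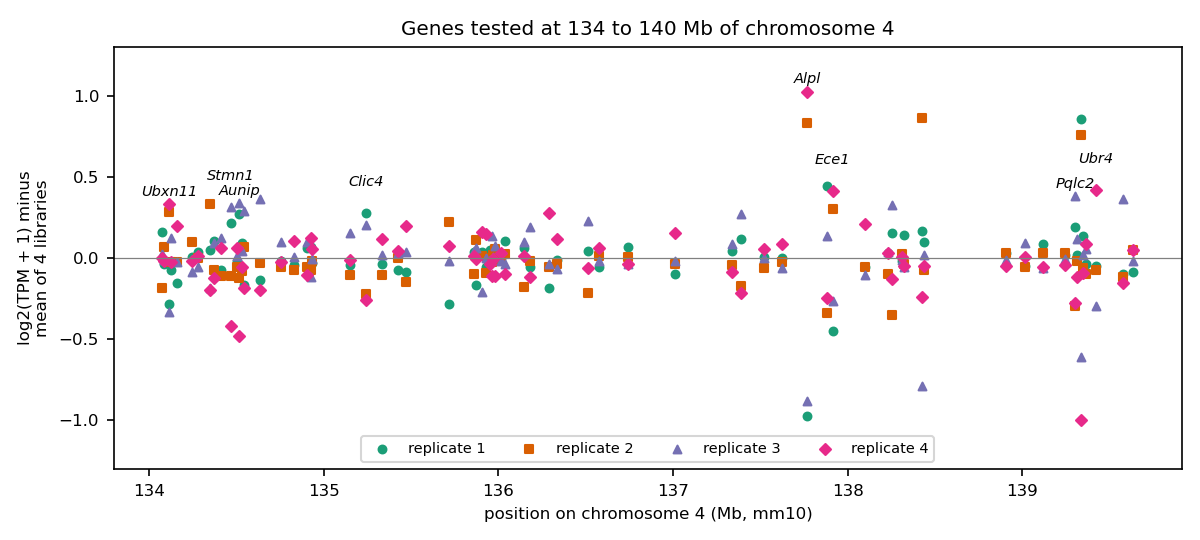
Each tested gene of a segment of chromosome 4 (horizontal axis, position in Mb, mm10) with its log2(TPM + 1) minus the mean of the 4 libraries on the vertical axis, a symbol per library; genes parted by more than 3 standardized units are named. Alpl lies at 21.4 and 22.9 TPM in replicates 1 and 3 and at 77.1 and 88.4 TPM in replicates 2 and 4.

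Of the 472 genes in the fixed lists 306 were tested, and 3 passed over all genes tested against 9 adjusted over the lists together. Over all genes these were Xist, Rpph1 (adjusted p = 0.00776) and the ribonucleotide reductase gene Rrm2 (adjusted p = 0.0289), the last chosen after its values were seen. Adjusted over the list alone, 8 of 22 cell cycle genes passed against 1 over all genes: Rrm2 at 147, 145, 183 and 119 TPM, Aurkb at 31.2, 29.9, 40.5 and 21.2 TPM, Ccna2 at 31.6, 34, 40.9 and 24.6 TPM, Mki67, Top2a, Cdk1, Ccnb1 and Birc5. Adjusted over the list alone, 6 of 7 tested mitochondrial genes passed against 0 over all genes, with mt-Cytb at 2036, 1718, 1873 and 2578 TPM. After removal of a length and GC trend, an alternative chosen after the data were seen, mt-Co1, mt-Cytb, mt-Nd4 and mt-Nd5 and the cell cycle gene Aurkb passed over all genes (edgeR adjusted p = 0.0025, 0.00187, 0.0336, 0.0113 and 0.0337). Il2, at 467, 406, 512 and 366 TPM, passed over the activation and cytokine lists alone (adjusted p = 0.00482 and 0.00193) and missed over all genes (adjusted p = 0.0773). In the structural RNA list 2 of 3 passed over the list alone, Rpph1 at 153, 286, 354 and 213 TPM and Rn7sk at 21.2, 16.5, 5.45 and 4.05 TPM. No member of the T cell receptor, CD4, helper, naive, glycolysis or interferon lists passed either way.

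As groups, 5 of 25 lists varied more between replicates than 10000 random lists of like abundance (two-sided permutation, Benjamini-Hochberg over the lists). These were the sex-linked list (median SD of log2 CPM 4.97 against 0.238 in random lists, adjusted permutation p = 0.00167), cell cycle (0.168 against 0.0801, adjusted p = 0.00167) and ribosomal proteins (0.0956 against 0.0637, adjusted p = 0.00167). The others were mitochondrially encoded proteins (0.195 against 0.0638, adjusted permutation p = 0.00375) and B cell genes (0.743 against 0.301, adjusted permutation p = 0.009). Genes of a list are not independent, so these values describe these 4 libraries. Without replicate 4 the cell cycle, mitochondrial and B cell lists no longer passed (adjusted permutation p = 0.717, 0.0875 and 0.722), and without replicate 1 the B cell list had p = 0.519 by the same permutation. Activation genes (0.0629 against 0.0651, adjusted permutation p = 0.913) and lymphocyte cytokines (0.0723 against 0.0713, adjusted permutation p = 0.95) did not pass. With the SD of log2(TPM + 1) the ribosomal protein and B cell lists no longer passed (adjusted permutation p = 0.088 and 0.0775). No list passed Fisher's exact test for holding more of the 28 genes after adjustment. For the sex-linked, structural RNA and cell cycle lists the unadjusted exact p was 0.00228, 0.00682 and 0.049. Their adjusted exact p was 0.0661, 0.0989 and 0.474. The sex-linked list had 1 tested member, Xist, so 0.00228 was the lowest p it could reach. With the count minimum in 1 library, chosen after the data were seen, 5 of 5 tested sex-linked genes passed (adjusted Fisher exact p = 2.11e-12). The Y-linked genes entered that test only through the libraries where they are high, and all 5 genes part the same libraries. They are not independent, so this p is no support for the list.

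Deviation from the mean of the libraries also changed with gene length, most strongly in replicate 4. The median deviation of its genes was -0.07 log2 CPM in the 987 shortest genes and 0.07 in the 986 longest. Replicate 2 ran the other way, from 0.0552 to -0.0444. Deviations from a shared mean are linked across libraries, so the trend cannot be placed in replicate 4 alone.

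**Figure D5:**
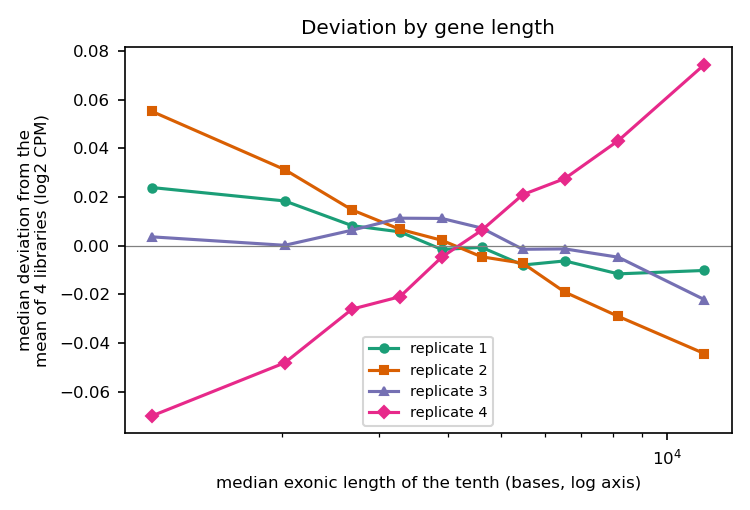
Median deviation from the mean of the 4 libraries in log2 CPM (vertical axis) for 9856 genes in 10 equal groups by exonic length (horizontal log axis), with a line per library. Replicate 4 runs from -0.07 in the shortest group to 0.07 in the longest, and replicate 2 from 0.06 to -0.04.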

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

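The tests of female and male mice, of mixed cells, of gain or loss of a segment and of depth on chromosome 4 were chosen only after the result was seen, and the window settings of the position scan were also set then; the other tests were written before.

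Single libraries stood apart from the other 3 in 11 of 162 values examined, where chance gives about 8.1; the figures in this paragraph are the gap to the nearest library divided by the whole range. In replicate 4 the read pairs held by the 10 most abundant genes were lowest (0.910), as were Ccl4 (0.900), Nkg7 (0.877) and Rps2 (0.933). Irf4 (0.877) and Bach2 (0.874) were highest there. In replicate 3 Cd40lg (0.967), and with it the median of the CD4 lineage list (0.967), and Mcm4 (0.912) were highest. In replicate 2 the median of the histone list was lowest (0.887), and in replicate 1 the median of the stromal list (1.00) lay above the others, all near 0.

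Xist and Y-linked transcripts parted the libraries. In 4 of 4 libraries either Xist or all of the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y reached 1 TPM and none of the other kind did. A mixture of cells of both sexes within a library is argued against, since the lower signal reached at most 0.313% of its highest library. Xist lay at 141, 116, 0.269 and 0.303 TPM in replicates 1 to 4. The mean of the 4 Y-linked genes lay at 0.0238, 0.082, 26.2 and 26.2 TPM. These values argue against a single animal as the source of all 4 libraries, although the biosamples share a donor identifier. A candidate explanation is that replicates 1 and 2 came from female mice and replicates 3 and 4 from male mice, and the labels give no sex to compare with. Gene differences between these libraries would then include sex, and no group tests this.

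In a segment of chromosome 4 from Crybg2 (start 134060815) to Aldh4a1 (end 139649690), 8 of 71 tested genes (11.3%, against 0.779% of other autosomal genes) had means of libraries 2 and 4 and of 1 and 3 parted by more than 3 standardized units, among them Alpl at 21.4, 77.1, 22.9 and 88.4 TPM and Stmn1 at 66.8, 53.1, 71.4 and 42.6 TPM. The segment was first noticed through a count of such parted genes, so these shares describe that choice and are no test of it. Ubr4 is counted among the 8 but lay at 78.9, 77.6, 66.3 and 109 TPM, high in library 4 alone. The scan's largest window held 50 of the 71 genes, without Ubxn11, Stmn1 and Aunip. Its chance placement is not excluded, since 0.0659 of permutations held a window as large. After removal of length and GC trends the share was 0.03. The window had not passed before that removal, so this share cannot test the trend and does not exclude chance. The window's mean squared contrast was 4.47 before the removal and 4.83 after it, which argues against such a trend as the source of its size. That comparison was not among the tests written before. Gain or loss of the whole segment is argued against, since 50% of the 8 genes moved in the less common direction. Lower depth is argued against, since the mean squared contrast of the window was 4.47 and after thinning to the smallest total 4.44 ± 0.0559 (SD, 20 thinnings). Windows elsewhere reached at most 3.06 before thinning and 3.12 in 1 thinning. The share of permutations (0.0779 in 1 thinning) did not pass either.

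Longer genes lay higher in library 4, with a Spearman correlation of 0.361 across 9856 genes between exonic length and the deviation from the mean of the libraries, against -0.121, -0.292 and -0.072 in libraries 1 to 3. Its 986 longest genes had a median deviation of 0.07 log2 and its 987 shortest genes -0.07. Because each deviation is taken from a mean shared by all libraries, the trend cannot be placed in library 4 alone. GC content is argued against (partial correlation 0.395 given GC), as are lower depth (0.361 after thinning) and a few very long genes (0.305 without the longest genes, a share of 10%). RNA quality and library preparation were not tested and stay open, and no biological explanation was tested.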

How the results depend on the processing

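Across the alternatives most values stayed on their side of the threshold or within their spread: 831 did so, 66 moved and 34 were no longer past a threshold, 28 of these for named spread genes. The deposited posterior mean TPM alternative was not run, since the files hold counts. Tests with a count minimum in 1 library, without X, Y and part of chromosome 4, with length and GC removed, and bias-adjusted were chosen after the data were seen. The cause of the changes below was not tested, except that fewer genes or libraries entered some of them. For replicate agreement the lowest Pearson r of 0.990 became 0.969 with pseudocount 0.1, 0.983 over genes at a mean of 1 TPM and 0.985 with log2 CPM. The coefficient of variation of 0.0881 became 0.109 without a filter and 0.0743 over nuclear protein-coding genes, and lay from 0.0801 to 0.0976 with a replicate left out. The 28 genes with excess spread became 142 without a filter, 80 by chi-square, 62 as DESeq2 dispersion outliers, 15 without a robust prior, 17 over nuclear protein-coding genes and 18 without X, Y and part of chromosome 4; leaving out a replicate gave 14 (replicate 3) to 27. At a floor of 5 TPM, detected members became 3 for Th1 and 7 for regulatory T cells. Lists past the spread threshold became 3 with the SD of log2(TPM + 1), and 2 (replicate 4) to 5 with a replicate left out. Lists enriched in spread genes, 0 in the main test and 3 at an unadjusted p under 0.05, became 5 without a filter, 1 with the count minimum in 1 library, and 0 to 2 with a replicate left out. In library composition the mean mitochondrial share of 0.568% of read pairs was 1.48% of TPM. No paired analysis was possible because there is 1 group. Depth limits genes under about 3 counts per library.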

Other observations

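The genes in this part were chosen after their values were seen. Variable segments of the T cell receptor were widely used: 61 of 128 Trav genes and 21 of 35 Trbv genes were at 1 TPM in every library, with summed CPM of 97.0 ± 3.28 and 171 ± 3.96 (SD, n = 4). Gamma chain V genes summed to 0.0102 ± 0.0204 and delta chain V genes to 0.827 ± 0.271 CPM. Immunoglobulin V genes were low, with 1.62 ± 0.377 CPM for Igkv and 0.320 ± 0.298 for Ighv, beside Ighm at 443 ± 18 TPM. Segments of 1 family share sequence, so these sums are uncertain.

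Several non-coding genes passed the spread threshold. Gm42418 lay at 3480.1, 2599.8, 1703 and 1596 TPM (adjusted p = 5.29e-06), Malat1 at 72.3, 43.8, 37.1 and 69.1 TPM (adjusted p = 0.000213), Gm26917 at 439, 612, 395 and 359 TPM (adjusted p = 0.00258) and Gm23935 at 7693, 8425, 5632 and 4985 TPM (adjusted p = 0.00222). Gm23935 spans only 11144125 to 11144181 on chromosome 16. It held 132, 145, 95.6 and 82.6 CPM, so its high TPM reflects its short length. Gm42418 and Gm26917 lie side by side on chromosome 17 (39846958 to 39848788 and 39843013 to 39846341). Where the reads of these genes came from was not tested. The peptide transporter gene Slc15a2 lay at 0, 0.0459, 2.75 and 2.58 TPM, with an adjusted p of 7.41e-06 from edgeR when the count minimum was needed in 1 library. On chromosome 15, near Bin2 and Tuba1c, Tuba1b lay at 642, 811, 673 and 756 TPM and Tuba1a at 58.2, 47.9, 62.5 and 43.5 TPM. Neither passed (edgeR adjusted p = 0.676 and 0.591). Tuba1b, like Bin2, was higher in replicates 2 and 4, where Tuba1c and Tuba1a were lower. Whether reads were shared between these tubulin genes was not tested, so their levels are uncertain.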
